A study of Drosophila melanogaster with 2 samples.

How the data were processed

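Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole larvae of Drosophila melanogaster of the third instar in the wandering stage, males and females together. The larvae carried an insertion that expresses CG32264 fused at its C terminus to green fluorescent protein (GFP), and the fusion protein was pulled down with an antibody against GFP, per the labels. Chromatin was broken by sonication into fragments of 200 to 800 bp, per the labels. The labels give 2 biological replicates, numbered 1 and 3, of 1 group, and no other condition. A control library is not analysed here, so no background measured in the same way stands beside the values.

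The deposited data used here are peak lists. For each replicate alone, and for both replicates together, there is a list of peaks and background regions made as input for an irreproducible discovery rate (IDR) analysis, a method that compares the ranks of peaks between replicates to set how many are kept. A further list holds the optimal set kept by the authors' IDR step. Each kind of list came in genome builds dm3 and dm6, and all coordinates given here are dm6, counted from 1. Per the deposited notes, each replicate's list was derived from that replicate's alignment and 1 further file, which is also a parent of the control-normalized signal track, and the list of both replicates together from both alignments and that file. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. Each list before IDR held 30000 peaks, with −log10 q down to 0.0824 in replicate 1 and 0.144 in replicate 3, so a limit on the list length is possible. The optimal set held 2546 peaks in dm6 and 2510 in dm3, and every one of its dm6 peaks was among the top 2546 of the list made from both replicates together. The peak signal is the authors' own value as deposited, on a scale that belongs to each list, and was used only to describe, rank and filter peaks within a list. The authors' lists also give each peak a q value as −log10, which ran from 2.66 to 3.63 in the optimal set and was not used in any test. Values of the list made from both replicates together have no SD and no number of replicates. The number of reads per library is not known from peak lists, so depth could not be compared, and a region without a peak is not shown to lack the protein.

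The dm6 lists were set against the RefSeq sequence of Release 6 of the genome and the Ensembl annotation BDGP6 (release 115 of Ensembl). On the 6 arms 2L, 2R, 3L, 3R, 4 and X, every dm6 peak ended within the length of the arm. Gene lists, motifs, tests, alternatives and the rule for naming genes were fixed before the data were examined. Overlap of replicates was the share of the top 2546 peaks of replicate 1, ranked by signal, that share at least 1 bp with a top 2546 peak of replicate 3. It was set against 1000 circular shifts of replicate 3 within arms (one-sided permutation test). Spearman's rho of the signal of the replicates was taken across regions, which are not independent replicates, with a Bonett-Wright interval and no p. The promoter share was the share of summits within 500 bp of an annotated transcription start, against 1000 circular shifts of the summits (two-sided permutation test). Locations of summits were set against 200 shifts. The strongest 25% of peaks were compared with the weakest 25% by Fisher's exact test, two-sided.

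A gene counted as having a peak when a summit of the optimal set lay within 500 bp of any of its starts. A gene with more annotated starts thus had more chances to count, and the tests did not adjust for this. Each of 24 gene lists was compared with all other genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 lists and a threshold of 0.05. Protein-coding lists were set against protein-coding genes, and the 2 lists of RNA genes against all genes. The lists were actin cytoskeleton, muscle structure, ecdysone response, salivary gland, fat body, neuron, glia, gut, hemocyte, cuticle and trachea, imaginal disc patterning, cell cycle, ribosomal proteins, oxidative phosphorylation, translation factors, heat shock and chaperones, chromatin regulators, insulin and TOR signalling, testis, chorion and yolk, chemoreceptors, tRNA genes, snRNA and snoRNA genes, and histone genes. Each of 19 sequence motifs was searched on both strands in the 201 bp centred on the summit and in a window of the same size 1100 bp to the left. The shares were compared by an exact McNemar test, two-sided, adjusted over the 19 motifs. Peaks per arm were compared with the share of protein-coding genes on the arm by an exact binomial test, two-sided, adjusted over 6 arms. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only. All these tests run over peaks, windows or genes of the 2 replicates, not over replicates, and neighbouring genes can share a peak, so the p-values do not measure the spread between larvae.

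Named genes followed this rule. The 25 peaks with the highest signal were named by the gene of the nearest start. Up to 4 members with the strongest peak were named for a list that passed its test, and up to 2 otherwise. CG32264, Mrtf and bs were named whether or not they had a peak, and so were the 3 strongest peaks of each replicate's top 2546 that overlap no peak in the whole list of the other replicate. A gene outside this rule is said to have been chosen after its values were seen.

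Alternatives covered the promoter window, the way a summit is assigned to a gene, the control window for motifs, the width of the motif window, the stronger 50% of peaks, each replicate's top 2546 peaks alone, the expected share by arm length, the overlap that counts as shared, and the dm3 lists. Limiting the peaks to those that overlap a top 2546 peak of both replicates, and the genes to those whose 51 bp around the 5′ end occur once in the assembly, was chosen after seeing the data. Steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data. With a single list, the ribosomal protein genes, planted among 18277 genes, it was called in 100% of 50 draws, with 0.06 false calls per draw. With a single motif planted in 2546 windows in 1 draw, it was called, with 0 false calls. These windows were placed at random over the arms. The motif simulation thus does not cover a difference in base composition between summit and control windows. Genes were drawn independently, so these simulations do not cover peaks shared by neighbouring genes. Smaller lists and weaker effects were not simulated.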

Results

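ChIP-seq peaks of GFP-tagged CG32264 were described in whole larvae of the third instar in the wandering stage, just before pupariation. CG32264 encodes a protein of the phosphatase and actin regulator family. The data were 2 biological replicates of 1 group, so the comparisons possible were between the replicates, between peaks, and between the peaks and the annotated genome. The optimal IDR set held 2546 peaks of 94 to 376 bp (median 376 bp), with a signal of 61.1 to 956 (median 90.2). Of the 30000 peaks of each replicate, the signal ran from 9.20 to 664 in replicate 1 and from 6.12 to 392 in replicate 3, on scales that belong to each list.

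The first question was whether the same regions were found in both replicates. The optimal set is the same as the top 2546 peaks of the list made from both replicates together, so the signal of its peaks draws on both. Each of the 25 highest peaks of the optimal set overlapped a top 2546 peak of both replicates, with ranks no worse than 27 in replicate 1 and 49 in replicate 3. The highest lay 29 bp from a start of Ugalt, a UDP-galactose transporter gene (X, 2703719 to 2704051, signal 956). The next were 93 bp from CG14100 (3L, 19590456 to 19590783, signal 947), in an intron of CG11050 (2L, 6612519 to 6612867, signal 885), in the 5′ UTR of PNPase, which encodes polynucleotide phosphorylase (3R, 31404519 to 31404818, signal 845), and in the 5′ UTR of CG1888 (2R, 9547018 to 9547357, signal 813). A peak inside an intron of ush had its nearest start at cbt, a zinc finger transcription factor gene (signal 761), and others lay in introns of the kinase gene Lk6 (757) and the Polycomb group gene ph-p (705).

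Across the top 2546 peaks of each list, 1559 of replicate 1 (61.2%, interval 59.3 to 63.1%) overlapped a peak of replicate 3. Circular shifts gave a mean of 1.29% and at most 2.40%, so the overlap was 47.3-fold above chance (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction 1582 peaks of replicate 3 overlapped (62.1%, interval 60.2 to 64.0%). Against the whole list of the other replicate, 2490 of the replicate 1 peaks (97.8%) and 2311 of the replicate 3 peaks (90.8%) had a partner. The whole lists hold background regions too (median −log10 q 0.227 in replicate 1 and 0.611 in replicate 3). No shifts were run against them, so how many partners would arise by chance is not known. Of the 2546 peaks of the optimal set, 2179 (85.6%) overlapped a top peak of replicate 1 and 1869 (73.4%) a top peak of replicate 3. Both held 1568 (61.6%), and 66 were in neither. Spearman's rho of the signal across the 2514 regions found in both lists was 0.501 (interval 0.469 to 0.531), all of them regions of the optimal set.

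The peaks of 1 replicate without a partner in the other list numbered 56 for replicate 1 and 235 for replicate 3, and 7 and 22 of these were in the optimal set. Since every list held exactly 30000 peaks, a limit on list length is possible, and a partner beyond such a limit would be missed. The strongest of replicate 1 lay at Blos3 (3L, 18870039 to 18870402, rank 656, in the 3′ UTR of the neighbouring Rad9), CG2656 (3R, 7144486 to 7144849, rank 857) and CG9143 (2R, 20278749 to 20279112, rank 1046). Those of replicate 3 were in the 5′ UTR of the nucleoporin gene Nup153 (X, 16599812 to 16600181, rank 257), in an intron of the ecdysone-induced gene Eip74EF with the nearest start at CycT (3L, 17563602 to 17563971, rank 426), and 95 bp from CG3165 (2L, 2976842 to 2977211, rank 430). Of the 235 peaks, 56 were on X, against 2 of the 56 of replicate 1. In the whole lists X held 3898 of 30000 peaks of replicate 1 (12.99%) and 5702 of 30000 of replicate 3 (19.0%), and among the top 2546 peaks the shares were 16.6% and 18.2%. These shares were looked at after the peaks were seen and set 1 library against 1 other, so they have no test of a difference between larvae. The shares of the whole lists also depend on where the lists end.

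The second question was where in the genome the peaks lay. Starts of genes held 1199 of 2546 summits within 500 bp (47.1%, interval 45.1 to 49.1%). Circular shifts gave 13.6% on average (central 95% of shifts 12.1 to 15.3%). The share was thus 3.47-fold above chance (two-sided permutation p = 0.002, the smallest that 1000 shifts can give). Within 100 bp of a start lay 475 summits (18.7%, against 3.26% by shifts), and 149 lay 10000 bp or more away (5.85%, against 23.8%). Among the 25 highest peaks, 13 were within 500 bp of a start, such as those of CG9147 (signal 682), Chro, a chromodomain protein gene (677), CenG1A (653) and CHMP2B, a component of the ESCRT-III complex (567). Farther away, 5 of the 25 were over 2000 bp from a start, including peaks in introns of CG32264 (2735 bp) and of Eip75B, a nuclear receptor gene induced by ecdysone (12102 bp, signal 540).

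Introns held 1340 summits (52.6%, against 42.4% by shifts), intergenic sequence 869 (34.1%, against 30.7%), 5′ UTRs 226 (8.88%, against 3.35%) and exons of non-coding genes 71 (2.79%, against 1.78%). Coding exons held 3 summits (0.118%, against 16.8%), at otp (2R, 20884393 to 20884768), Zir (2L, 94687 to 95062) and Trxr1 (X, 8244300 to 8244675), which were named after their values were seen. In the top 2546 peaks of replicate 1 there were 5 (0.196%) and in those of replicate 3 there were 10 (0.393%). Summits in 3′ UTRs numbered 37 (1.45%, against 4.92%). The two-sided permutation p was 0.0299 for intergenic sequence and 0.00995, the smallest that 200 shifts can give, for each of the other locations. Outside promoters, introns held 978 of 1347 summits (72.6%, against 45.4%) and coding exons held 1 (0.0742%, against 15.9%). There, intergenic sequence held fewer summits than by shifts (312, 23.2% against 31.7%, permutation p = 0.00995), and exons of non-coding genes did not differ detectably (1.26% against 0.936%, permutation p = 0.169).

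**Figure D1:**
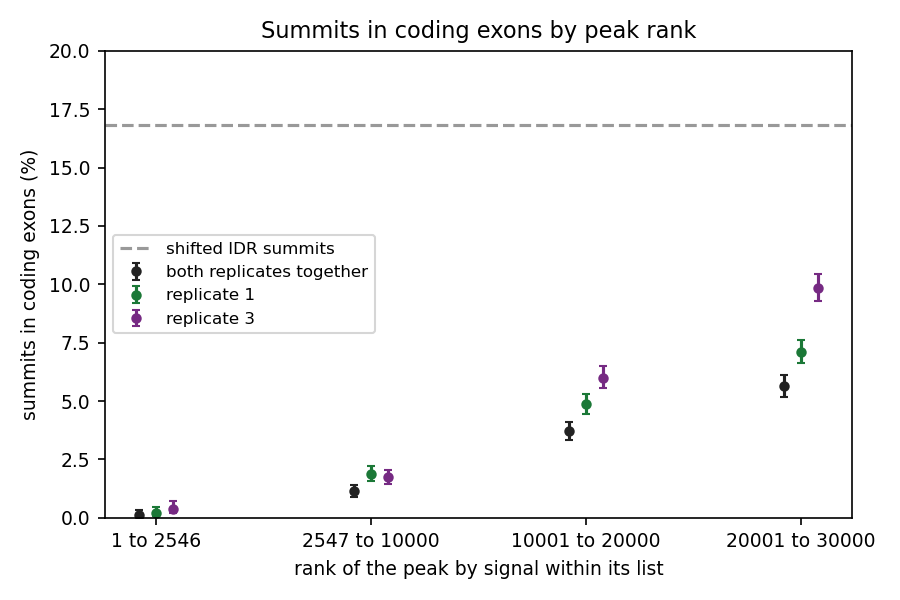
Share of summits in coding exons in percent (vertical axis) by peak rank (horizontal axis) for each replicate and for both together, with exact 95% intervals and the 16.8% of shifted summits as a dashed line. In the list made from both replicates together the share was 0.118% in the top 2546 peaks and 5.63% in the weakest 10000.

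Strong and weak peaks did not differ detectably in promoter share. Starts lay within 500 bp of 50.6% of the strongest 636 peaks, which include those of Ugalt, PNPase and Chro, and of 45.9% of the weakest 636 (odds ratio 1.21, Fisher's exact p = 0.104). With the peaks of replicate 1 alone the odds ratio was 1.25 (Fisher's exact p = 0.0496), and with those of replicate 3 alone 0.904 (p = 0.400), and the difference between these odds ratios was not tested. Among the 1568 peaks found in both top lists, a set chosen after seeing the data, the shares were 51.02% and 41.6% (odds ratio 1.46, Fisher's exact p = 0.00988).

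The third question was which groups of genes carried peaks at their starts. A peak lay at a start of 1597 of 18277 genes, including 1450 of 13968 protein-coding genes (10.4%). Of the 24 gene lists, 5 had more genes with a peak than other genes did, 4 had fewer and 15 did not pass the test. Ribosomal protein genes had the lowest p: 37 of 93 had a peak (39.8%, odds ratio 5.85, adjusted exact p = 2.21e-12), among them RpL32 (3R, 30046164 to 30046308, signal 242), RpL7 (227), RpS27 (209) and RpL14 (180). Regulators of chromatin followed with 13 of 36 (36.1%, odds ratio 4.99, adjusted exact p = 0.000288). Their strongest peaks were at ph-p (X, 2137204 to 2137510, signal 705), Chro (3L, 22878738 to 22879047, signal 677), brm, the ATPase of the SWI/SNF complex (176), and Cp190, an insulator protein gene (166).

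Actin cytoskeleton genes had a peak in 15 of 47 cases (31.9%, odds ratio 4.15, adjusted exact p = 0.000295). Examples were shot, a spectraplakin that links actin and microtubules (2R, 13925391 to 13925766, signal 202), the vinculin gene Vinc (141), the paxillin gene Pax (111) and the moesin gene Moe (103). Heat shock and chaperone genes had a peak in 10 of 32 cases (31.3%, odds ratio 4.05, adjusted exact p = 0.00366), led by Hsp27 (3L, 9383752 to 9384046, signal 512), with Hsp26 (172), Hsp83, the fly Hsp90 (169), and CG11267, listed under its synonym Hsp10 (79.1). Genes of the ecdysone response, the steroid programme that starts metamorphosis, had a peak in 10 of 36 cases (27.8%, odds ratio 3.44, adjusted exact p = 0.00763). These included the transcription factor gene Sox14 (2R, 23978421 to 23978689, signal 469), the cell death gene hid (219), Eip75B (217) and E23, an ABC transporter gene (135).

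Several of these calls depended on the peaks used. With the stronger 50% of peaks, which leaves fewer genes with a peak, the odds ratio was 1.83 for actin cytoskeleton (adjusted p 0.599), 2.45 for ecdysone response (0.375), 2.10 for heat shock and chaperones (0.592) and 3.78 for chromatin regulators (0.0549). Among peaks of both top lists, chosen after seeing the data, it was 2.84 for actin cytoskeleton (0.0814), 2.67 for ecdysone response (0.203) and 1.81 for heat shock and chaperones (0.699), and with a window of 250 bp it was 1.54 for ecdysone response (0.714). Without replicate 3 it was 2.43 for ecdysone response (0.116) and 1.63 for heat shock and chaperones (0.550), while cell cycle genes passed (10 of 37, odds ratio 3.12, adjusted exact p = 0.0157).

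The lists with fewer peaks were chemoreceptors, with 0 of 179 genes (interval up to 2.04%, against 10.5% of other protein-coding genes, adjusted exact p = 4.66e-08), small nuclear and nucleolar RNA genes, tRNA genes and histone genes. Of the snRNA and snoRNA genes 9 of 301 had a peak (2.99%, against 8.83%, adjusted exact p = 0.000338), such as snoRNA:Psi28S-2949 (signal 128). With a window of 1000 bp the odds ratio was 0.871 (adjusted p 0.711), against 0.335 with 500 bp. Among tRNA genes 11 of 290 had a peak (3.79%, against 8.82%, adjusted exact p = 0.00455), the strongest at tRNA:Tyr-GTA-1-8 (signal 226), with an odds ratio of 0.425. Without replicate 1 it was 0.726 (adjusted p 0.383), and with the stronger 50% of peaks 0.402 (adjusted p 0.0601). Both lists of RNA genes were set against all genes, most of which are protein-coding. Of the genes annotated as ncRNA, 123 of 3289 had a peak (3.74%), near the shares of both lists. The 2 calls are therefore not shown to be particular to these lists among non-coding genes. Histone genes had 1 peak among 116 (0.862%, against 10.5%, adjusted exact p = 0.000338), at His2Av, which encodes the H2A variant (signal 84.3). Most histone genes are near-identical copies: 8 of the 116 have a start that occurs once in the assembly, 1 of the 8 had a peak, and with such genes alone, a choice made after seeing the data, the odds ratio was 1.68 (Fisher's exact test, adjusted exact p = 0.791).

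Genes that mark single tissues did not pass the test. Peaks lay at 2 of 34 neuronal genes (elav, signal 181, and Fas2, 68.2), 2 of 19 glial genes (moody, 169, and Gli, 90.4), 2 of 25 fat body genes (Lpin, 403, and GNBP3, 122), 1 of 34 muscle structure genes (Msp300, 195), 1 of 18 salivary gland genes (fkh, 308), 1 of 27 gut genes (Myo61F, 75.0), 1 of 21 hemocyte genes (ush, 124) and 1 of 25 testis genes (bgcn, 66.8). Cuticle and trachea genes had 0 of 35 (raw p = 0.0458, adjusted exact p = 0.110, Fisher's exact test; adjusted p 0.0482, lower, with a window of 1000 bp) and chorion and yolk genes 0 of 18. In imaginal disc patterning 3 of 48 genes had a peak, including Dll (86.8) and Egfr (76.4), with 0 of 48 without replicate 3 (adjusted exact p = 0.0225) and 7 of 48 without replicate 1 (adjusted p 0.391). The remaining lists were cell cycle with 6 of 37 (Dp, 112, and aurA, 95.9), oxidative phosphorylation with 10 of 84 (ND-ASHI, 166, and ND-MWFE, 120; 3 of 84 without replicate 1 and 12 of 84 without replicate 3, neither past the test), translation factors with 8 of 52 (eIF6, 455, and eEF1gamma, 139) and insulin and TOR signalling with 3 of 24 (Pi3K21B, 208, and InR, 95.6). Adjusted p in these 15 lists was 0.110 or more.

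**Figure D2:**
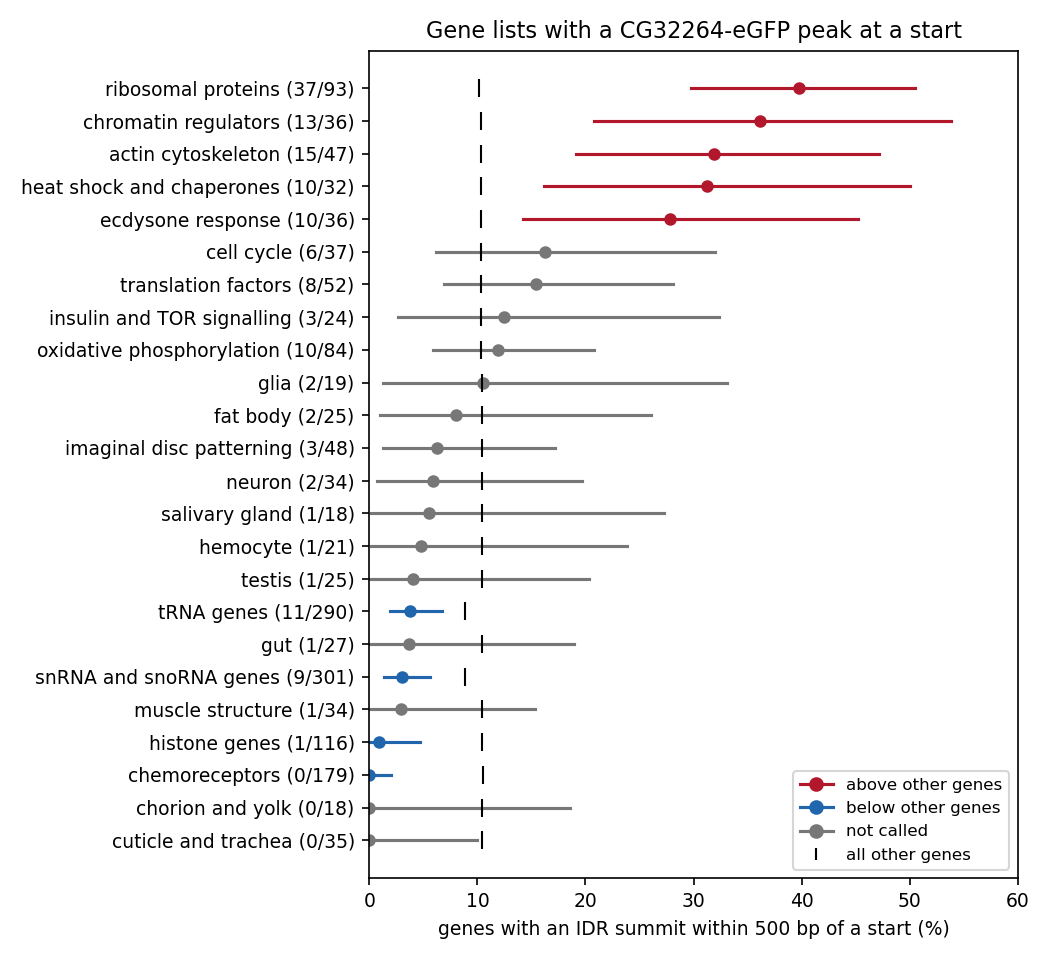
Share of genes with a peak within 500 bp of a start, in percent (horizontal axis), for each of the 24 gene lists (vertical axis), as points with exact 95% intervals, coloured by call, with a tick at the share of all other genes. Ribosomal protein genes stood at 39.8% and chemoreceptors at 0%, against 10.4% of all protein-coding genes.

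The tagged gene and a pair of genes of actin-regulated transcription were looked at by name. CG32264 (FBgn0052264, 3L, 3714826 to 3806459, minus strand) held 6 summits of the optimal set, all in introns. The strongest, of rank 20, was at 3785091 to 3785363 (signal 568, ranks 22 and 19 in replicates 1 and 3), and 1 lay 108 bp from a start (rank 1587, signal 79.9). Circular shifts gave a mean of 1.79 summits in the gene (permutation p = 0.0864, 10000 shifts). Mrtf, an actin-binding transcriptional coactivator (3L, 2717615 to 2766536), held 0 summits of the optimal set, and its best peak in the list made from both replicates together had rank 3825. Its DNA-binding partner bs, the fly serum response factor (2R, 24342861 to 24376473), held 1, in an intron (24363510 to 24363607, rank 481, signal 149).

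**Figure D3:**
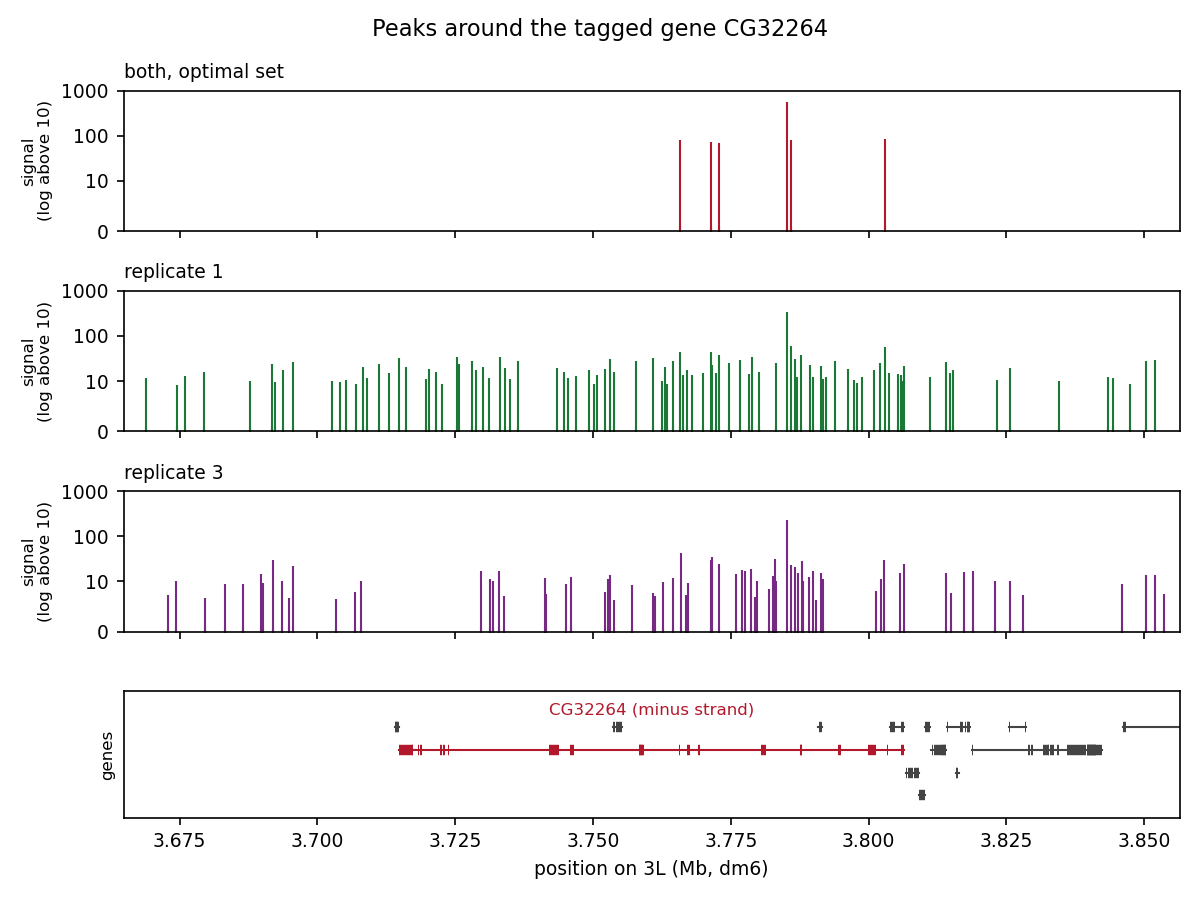
Summits around CG32264 on 3L (dm6 position in Mb along the horizontal axis), each line as high as the authors' signal (vertical axes, logarithmic above 10), for the optimal set and each replicate, over the exons of CG32264 (red) and its neighbours. The gene holds 6 summits of the optimal set, 68 of the list of replicate 1 and 50 of that of replicate 3.

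The fourth question was which sequence motifs lay at the summits. Of the 19 motifs, 5 were more frequent at summits than 1100 bp to the left and 1 was less frequent. The site of the muscle regulator Mef2 was in 10.9% of 2546 windows against 5.93% (odds ratio 1.97, adjusted exact p = 2.61e-09), and the DNA replication-related element bound by Dref and BEAF-32 in 2.95% against 0.746% (odds ratio 3.87, adjusted exact p = 4.58e-08). The GAGA element bound by Trl was in 6.01% against 3.53% (odds ratio 1.75, adjusted exact p = 0.000179), the GATA site in 37.5% against 32.2% (odds ratio 1.26, adjusted exact p = 0.000291) and the homeodomain core in 14.6% against 11.0% (odds ratio 1.38, adjusted exact p = 0.000564). The site of the Polycomb recruiter Pho was in 1.41% against 3.22% (odds ratio 0.421, adjusted exact p = 0.000104). The CArG box, the site of serum response factor, was in 0.864% against 1.14% (odds ratio 0.763, adjusted exact p = 0.608), and no difference was detectable. GC content was 36.9% ± 6.46 (SD over 2546 windows) at summits and 42.6% ± 9.24 to the left. At the top 2546 summits of each replicate alone it was 36.1% in replicate 1 and 39.2% in replicate 3. Whether this goes with the differences between replicates given below was not tested.

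The odds ratio of GAGA was 1.19 without replicate 3 (adjusted p 0.342) and 3.21 without replicate 1 (4.99e-23), and that of GATA was 1.15 without replicate 1 (0.0547) and 1.22 without replicate 3 (0.00326). That of the Dref element was 2.16 without replicate 1 (0.00807) and 3.34 without replicate 3 (4.36e-08). GAGA was at 1.22 against the window to the right (0.194), 1.27 with the stronger 50% of peaks (0.427) and 1.36 with the peaks of both top lists (0.263), and the Dref element at 2.30 with the stronger 50% (0.0763). Against the window to the right the M1BP element (2.10, adjusted exact p = 0.0478) and the TATA box (1.48, 0.0294) were more frequent at summits. The STAT site (0.515, 0.0186) and the nuclear receptor half-site (0.638, 0.00490) were less frequent there. Without replicate 1 the M1BP element (odds ratio 2.84, adjusted exact p = 0.00414) was more frequent and the nuclear receptor half-site (0.595, 0.00272) less frequent at summits. Without replicate 3 the M1BP element (1.89, 0.0356), the TATA box (1.43, 0.0491) and the initiator (1.16, 0.0289) were more frequent, and the CA repeat (0.546, 0.0193) and the nuclear receptor half-site (0.709, 0.0356) less frequent. Against starts of protein-coding genes with no peak, the Dref element was not more frequent at promoter summits (odds ratio 0.776, adjusted exact p = 0.0818), while the M1BP element (0.304, adjusted exact p = 2.15e-11), the TATA box (0.668, adjusted exact p = 0.00276) and the initiator (0.672, adjusted exact p = 4.67e-10) were less frequent, and the Pho site was at 0.629 (adjusted p 0.0980). More frequent against the same starts were Mef2 (2.12, adjusted exact p = 1.64e-12), homeodomain (1.70, 9.64e-09), GAGA (2.05, 2.85e-07) and GATA (1.27, 0.000501) sites, the CA repeat (2.18, 0.00276) and the CTCF core (2.22, 0.0336). Those windows are centred on starts, while 475 of the 1199 promoter summits lay within 100 bp of one, so elements placed at starts are expected to be fewer at summits and this control is uneven in position.

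**Figure D4:**
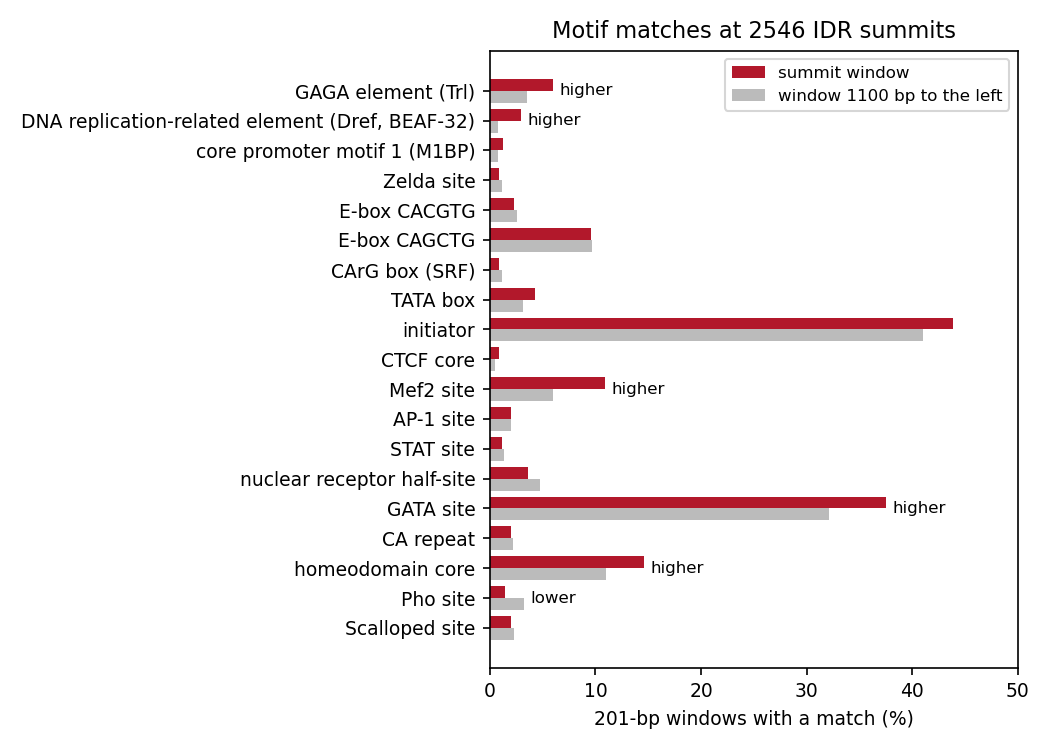
Share of windows with each motif, in percent (horizontal axis), centred on summits or 1100 bp to the left, for the 19 motifs. Mef2 sites stood at 10.9% at summits and 5.93% to the left, and Pho sites at 1.41% and 3.22%.

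The last question was how the peaks were spread over the chromosome arms, since a pool of both sexes has fewer copies of X than of an autosome. X held 425 of 2546 summits (16.7%, interval 15.3 to 18.2%) with 15.7% of protein-coding genes, 1.06-fold the expected share (exact binomial adjusted p = 0.273), and without replicate 1 it was 1.16-fold (adjusted exact p = 0.00419). Chromosome 4 held 8 summits, 0.549-fold (adjusted exact p = 0.174), and was below its share when either replicate was used alone (0.343-fold without replicate 1, adjusted exact p = 0.0158, and 0.411-fold without replicate 3, adjusted exact p = 0.0354, exact binomial test). It also passed as lower by arm length (0.321-fold, adjusted exact p = 0.00100) and, chosen after seeing the data, with the peaks of both top lists (0.223-fold, adjusted exact p = 0.0226), but not with the stronger 50% of peaks (0.274-fold, adjusted p 0.117). On 3L there were 554 summits, 1.11-fold (adjusted exact p = 0.0210), and on 2R 458, 0.881-fold (adjusted exact p = 0.0137). Neither passed with the share expected by arm length (3L 1.065-fold, adjusted p 0.199, and 2R 0.979-fold, 0.627) or with the stronger 50% of peaks (1.098-fold, 0.135, and 0.873-fold, 0.0693). Arms 2L with 492 and 3R with 609 did not pass the test, but by arm length 2L was 1.13-fold (adjusted exact p = 0.00956), and 3R was 0.924-fold without replicate 1 (adjusted exact p = 0.0343).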

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

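The tests of 8-base words, of shuffled control windows and of copies of the tagged locus were chosen only after the result was seen, and the others were written before. Outside the main measurement, the dm3 lists hold peaks beyond the 6 assembled arms. The reference was a count of 0, which is not a measured expectation, since no control library was analysed. Such peaks numbered 120 in replicate 1, 39 in replicate 3 and 67 in the list made from both. In replicate 1 the contig 3LHet had 48 of them, and the best rank in replicate 3 was 306, for the single peak on the mitochondrial contig M. None was in the optimal set.

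Summits were rich in A and T, as were some motifs enriched there, and the homeodomain core and the GATA site were at 0.910 and 0.952 of the mean of 100 shuffles of the summit windows that keep dinucleotides, so composition may account for both. The Mef2 site was at 1.41 times the shuffles, above all of them, but so was the E-box CAGCTG, at 2.89 times, which was no more frequent at summits. With the control windows shuffled as well, the summit to control ratio of Mef2, 1.83, was within the shuffles (mean 1.63, at most 2.23). Composition and other sources of the Mef2 difference therefore cannot be told apart. By the same measure the ratio of GAGA, 1.70, was above all shuffles (at most 1.15). That of the Pho site, 0.442, was below all of them (at least 0.826). For the Dref element the ratio, 3.87, was below the highest of its shuffles, 15, but most of them stayed below 3.15. Matches were few there, with a mean of 5.65 windows in the shuffled controls. Its summit windows were at 10.6 times their own shuffles and its control windows at 3.36 times theirs. The ratio therefore cannot decide whether composition gives the Dref difference. Composition thus falls short for GAGA and Pho against this control window, but the GAGA call was kept in only 3 of 7 settings. Of 10 words of 8 bases picked on chromosomes 2 and 4, 10 passed on 3 and X, which argues against picking by chance. Several of the words share bases, so these are not 10 independent tests, and words favoured by composition alone could pass too. Composition falls short for words with at least 3 G or C in sum (5.81 times the shuffles, and a ratio of 5.51 against at most 1.49). Of these words GCGAGAAA alone, at 1.85, was within its shuffles. Words with at most 1 were at 1.31 times in sum (ratio 1.85 against at most 1.72), but of these 6 only AGAAAAAT exceeded the highest ratio on its own (2.35 against 1.84), so composition may account for part of them. No biological explanation was tested.

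Summits were scarce in coding exons, with 0.118% in the optimal set and 0.196% and 0.393% in the top 2546 peaks of replicates 1 and 3. Low GC content falls short as the whole cause, since random positions of the same GC content gave 6.44% on average and at least 5.38%. Removal of coding exons from the lists as a whole is also argued against, since 5.63% of the weakest 10000 summits of the list made from both replicates lay there. No biological explanation was tested, and accessibility of chromatin, which was not measured here, stays open.

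CG32264 itself held many weak peaks as well as the peak of rank 20. Its weak peaks, 6.88 per 10 kb, were at percentile 99.3 of 285 protein-coding genes of 50 to 150 kb, and 1 of these genes, sbb, was denser. The 50 kb on either side had 3.8 and 1.6 per 10 kb. Extra copies of the locus, binding of the protein to its own gene and other sources of weak peaks cannot be told apart. A high density goes with extra copies or with binding, and sbb, which is not the tagged gene, was denser still. The labels used here leave open whether the transgenic line carries an extra copy. No biological explanation was tested.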

How the results depend on the processing

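The peaks found in both top lists and the genes with a unique start were alternatives chosen after seeing the data, and the others were planned. Overlap of the replicates was 54.7 to 66.8% and the rank correlation, which has no test, 0.501 to 0.526. The promoter share was 37.0 to 59.4% and above the shifts in all settings run. The 25 highest peaks were found with either replicate left out. Of 192 values of single lists 175 had the same call as the main setting, 14 values of 7 lists lost it and 3 gained one. Of 133 values of single motifs the numbers were 108, 8 and 17, and of 20 values of the arms other than X and 4 they were 14, 4 and 2.

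With the stronger 50% of peaks, 1 list was above background in place of 5, and 3 motifs were enriched in place of 5. With the peaks of both top lists, 2 lists were above background, the odds ratio of strong against weak peaks was 1.46 and chromosome 4 was at 0.223 of its share. Motifs less frequent at summits were 3 with the control window to the right, 3 against starts without a peak, 2 with 50 bp either side and 2 to 3 with a replicate left out, in place of 1. By arm length, chromosome 4 was at 0.321 and X at 0.975. With a replicate left out, the odds ratio of strong against weak peaks was 0.904 to 1.25, chromosome 4 was at 0.343 to 0.411 and X at 1.06 to 1.16. Values that crossed 1 with a call on either side were histone genes with unique starts (odds ratio 1.68, with 8 genes left to test) and, against starts without a peak, the Dref element (0.776), M1BP (0.304), TATA box (0.668), initiator (0.672) and CA repeat (2.18). That control is centred on starts and most promoter summits are not, so it is uneven in position, and the cause was not tested.

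Leaving out a replicate means the top peaks of the other list, since IDR needs both. It gives no value for overlap and rank correlation. The top of the list made from both replicates is the same set of peaks as the optimal set and has no value of its own. No paired analysis was possible because there was 1 group. Read depth is not known from peak lists, and 2 replicates allow no test of the spread between larvae.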

Other observations

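All values in this part were chosen after the result was seen. Several genes held many summits of the optimal set within their bodies. Eip75B had 12 in 114 kb, 5.55-fold the number given by its length. The genes sbb and shn, which encode nuclear regulators of transcription, had 12 each (7.98-fold and 10.8-fold), kirre had 13 in 394 kb (1.73-fold), and Trl, which encodes the GAGA factor, had 5 in 13.1 kb (20.04-fold). The 50 kb with the most summits, 13, was on 3R at 30250001 to 30300000 and includes heca. These folds have no test.

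The 4 words with at least 3 G or C were CACTGAGA, TCAGTGCA, AGTGTTGG and GCGAGAAA. On the other strand TCAGTGCA reads TGCACTGA, which shares CACTGA with CACTGAGA, so these words may be parts of a longer one. On chromosomes 3 and X, CACTGAGA was in 61 summit windows without a match in the control window, and in 5 control windows without a match at the summit (adjusted p = 2.63e-12, exact McNemar test). TCAGTGCA gave 65 against 9 (adjusted exact p = 6.75e-11), AGTGTTGG 39 against 5 (4.68e-07) and GCGAGAAA 29 against 15 (0.0488). At least 1 of the 4 was in 290 of 2546 summit windows (11.4%) and 51 control windows (2.003%), which include the arms where the words were picked. Counted on 3 and X alone, it was in 169 of 1588 summit windows (10.6%) and 34 control windows (2.14%). In the 91 windows where at least 6 bases on each side of CACTGAGA lay within the window, it had A at positions 2 and 3 after the word in 85.7% and 90.1%. At position 4 after the word A stood in 75.8%. Before the word it had G at position -1 in 49.5%, with A there in 44.0%, and T at position -2 in 54.9%. The highest-ranked peaks holding a word include those at CG11050 (rank 3), Lk6 (rank 7) and Sox14 (rank 32). Strong and weak peaks did not differ detectably in the share with a word. On 3 and X it was 10.1% in the strongest 397 peaks and 11.8% in the weakest 397 (odds ratio 0.834, Fisher's exact p = 0.496). On 3 and X the share was 9.29% in promoter peaks and 11.8% in others (Fisher's exact p = 0.121). In the top peaks of replicate 3 alone, GCGAGAAA did not pass (35 against 21, exact p = 0.0814).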
